A study of Mus musculus with 12 samples.

How the data were processed

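RNA was measured by sequencing in 12 libraries of leukemic long-term hematopoietic stem cells (LTHSC), 4 libraries in each of 3 groups named No_Cre, Tek_Cre and Prx1_Cre after the Cre line of the mice the cells came from. Per the labels' protocols, the cells were sorted by flow cytometry with conventional cell surface markers from bone marrow of C57BL/6 mice with chronic myeloid leukemia, total RNA was made into libraries with a SMARTer ultra low input kit and Nextera XT, and the groups held biological replicates. The labels call the mice both recipient and primary mice, and state neither the leukemia model nor the genotype at Cxcl12. Per the submitters' processing notes, which name tools without roles or order, Trim Galore 0.4.4, STAR 2.5.3a, HTSeq 0.9.1 and DESeq2 1.18.1 were used with genome build GRCm38; the annotation release, the strand setting and any filter are not stated.

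The authors deposited a single table of raw counts per gene, with 48795 versioned Ensembl gene identifiers and 1 column per library. All 12 columns were whole numbers and all were used. Symbols were matched by identifier without version for 48349 genes, 41341 of them with the same version, and 446 identifiers had no match. Where a symbol belonged to more than 1 identifier, as for 63 symbols, the identifier with the most counts was taken. Coordinates are those of the GENCODE M21 annotation on GRCm38. Counts of gene families with near-identical members (immunoglobulin V genes, the hemoglobin genes, H2 genes) depend on how reads shared between members were assigned, which is not stated. Whether reads of a BCR-ABL1 transgene, if the model carries one, were counted at Bcr and Abl1 is not known, and reads of an antisense or overlapping gene could not be told from those of the named gene.

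Total counts ran from 15715603 to 28860324 per library. Values are given as CPM, counts scaled to the library totals and by trimmed mean of M-values (TMM) factors, as mean ± SD over the 4 libraries of a group. A group without a count was set to a floor of 3 counts over the group, and a fold against it is written as at least that fold. Floors cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

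Groups were compared with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test (robust fit), TMM factors, a term for the group alone and all 12 libraries in 1 fit. The filterByExpr function left 14756 genes. P-values were adjusted by Benjamini-Hochberg over the genes tested within a comparison, and genes under an adjusted p of 0.05 are described as having risen or fallen. Changes are log2 fold changes ± SE. A set of 34 gene lists with at least 5 members tested was compared with camera (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the lists within a comparison, beside camera with an estimated correlation and fry on the same fit. In the lists, 6 of 998 genes had no match. For each list the calls were also adjusted over the list alone. Library measures (total counts, genes detected, the share of mitochondrially encoded genes and of the 20 most abundant genes) were compared by two-sided exact permutation tests of the difference of means, for which 0.0286 is the smallest p that 4 against 4 libraries allow, adjusted over 12 tests. Plots were drawn with matplotlib 3.10.9 in Python.

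The lists were S phase, G2/M, MYC targets, quiescence, the PRC2 complex, DNA replication and repair, p53 targets, apoptosis regulators, TGF-beta and Wnt signalling, output of BCR-ABL, STAT5 and RAS, NF-kB and TNF, interferon response, antigen presentation and MHC, adhesion and homing, nuclear oxidative phosphorylation, glycolysis, hypoxia, cholesterol biosynthesis, cytosolic ribosome, heat shock and unfolded protein response, 11 lists of cell types (LTHSC, multipotent progenitor, megakaryocyte, erythroid, neutrophil, monocyte with macrophage and dendritic cell, mast cell with basophil and eosinophil, B cell, T and NK cell, endothelial, stroma), and the mitochondrially encoded and immediate early genes as quality lists. Named genes were, per comparison, 8 niche axis genes (Cxcl12, Cxcr4, Ackr3, Ezh2, Abl1, Bcr, Cdkn1a, Mki67), the 8 largest changes up and the 8 largest down among called genes with a mean of at least 5 CPM and no overlap between the libraries of the 2 groups, and the 3 members of smallest p in the direction of each called list. Gene models without a proper symbol and pseudogenes were passed over. The text gives a part of these in full, and some are not reported here.

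The groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. Chosen after the values were seen were the test against a 2-fold change (glmTreat), the fit without the 429 immunoglobulin genes, of which 147 were tested, the largest changes outside these genes, 6 marker lists (plasma cell, eosinophil, early and late erythroid, sex-linked, core LTHSC), the use of Ig kappa V genes, and the named genes Cpa3, Cma1, Mmp8, Mzb1, Sdc1, Xbp1, Mecom, Procr, Hlf, Xist and Ddx3y. Chosen then, too, were Irf4, Jchain, Igkc, Tpsb2, Mpo, Ctsg and Elane in Tek_Cre against No_Cre, and Epx and Prg2 in Prx1_Cre against Tek_Cre.

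Alternatives were RLE and upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no filter on low counts, a stricter filter (at least 20 counts in at least 4 libraries), only the 8 libraries compared, a block for the replicate number, the number of genes detected as a covariate, and leaving out each library in turn. The comparison was also tested on simulated data with known changes, in which 78.0%, 79.6% and 80.8% of genes changed 1.5-fold were recovered in the 3 comparisons and 0 of 33 unchanged lists were called. Of genes changed 1.2-fold, 45.8%, 34% and 39.8% were recovered, and 8.72%, 5.88% and 4.66% of the genes called were false. The simulated genes were drawn independently of each other, so lists with correlated members were not tested. Weakly expressed genes were raised to a minimum mean count before the simulation, so recovery may be lower for such genes in the data. Far fewer genes were changed than were called in the data, so these rates need not carry over. Upper-quartile factors moved the median log2 fold change of all genes to -0.11 in Prx1_Cre against No_Cre and to -0.0895 in Prx1_Cre against Tek_Cre, so small changes in these comparisons are relative to that shift.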

Results

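The series measured the RNA of leukemic LTHSC, the population at the top of blood cell formation, sorted from the bone marrow of 3 groups of mice. No_Cre mice carried no Cre, Tek_Cre mice a Cre active in endothelial and blood-forming cells, and Prx1_Cre mice a Cre active in mesenchymal stroma. The series title names the Cxcl12 made by the mesenchymal niche and the quiescence of treatment-resistant leukemia stem cells, so the comparisons ask how the sorted cells differed with the Cre line of the mouse. Each group had 4 libraries. Total counts per library ran from 19988050 to 24007569 in No_Cre, from 15715603 to 28860324 in Tek_Cre and from 22385590 to 28253956 in Prx1_Cre. Values are given as mean ± SD over the 4 libraries of a group.

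The groups differed in what the libraries held. Immunoglobulin genes took 7.45 ± 0.175% of counts in No_Cre, 25.7 ± 0.356% in Tek_Cre and 0.301 ± 0.00586% in Prx1_Cre. The 20 most abundant genes took 12.3 ± 0.124%, 26.5 ± 0.409% and 8.70 ± 0.0937% in the same order, and 21016 ± 246, 19676 ± 627 and 20181 ± 423 genes had at least 1 count. Mitochondrially encoded genes took 0.133 ± 0.0111%, 0.115 ± 0.0107% and 0.388 ± 0.0743%. In two-sided exact permutation tests the share of the 20 most abundant genes differed in all 3 comparisons, the number of genes detected differed between No_Cre and each other group, and the mitochondrial share differed between Prx1_Cre and each other group (p = 0.0286, the smallest possible, adjusted p = 0.0490 for each). Total counts did not pass in any comparison (exact p = 0.171 for Prx1_Cre against No_Cre, 0.743 for Tek_Cre against No_Cre and 0.714 for Prx1_Cre against Tek_Cre). Neither did the genes detected in Prx1_Cre against Tek_Cre (exact p = 0.286) or the mitochondrial share in Tek_Cre against No_Cre (exact p = 0.0857).

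Libraries of a group were close to each other, with Prx1_Cre replicate 4 the farthest from its group (chi-square per degree of freedom 11.5 to 14.3 in its 3 pairs within the group, 1.80 to 7.80 in the other 15 pairs within groups). The common biological coefficient of variation was 3.45% in No_Cre, 5.32% in Tek_Cre and 6.81% in Prx1_Cre. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.993 to 0.996 for the 18 pairs of libraries within a group and 0.865 to 0.927 for the 48 pairs between groups. The 2 leading principal components carried 68.0% and 25.5% of the variance and set the 3 groups apart. The p-values given for genes and lists measure the spread between these libraries alone, and whether that spread holds differences between mice is weighed in the closing section.

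**Figure D1:**
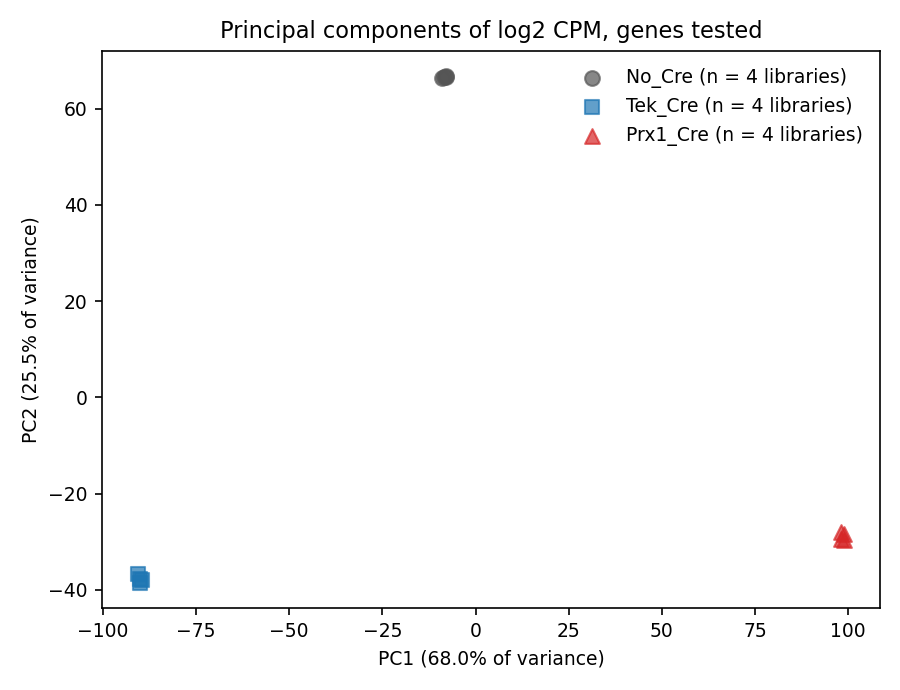
Principal components of log2 CPM over the 14756 genes tested, each point 1 library, with the 4 libraries of a group in 1 colour and shape. PC1 (68.0% of the variance) sets Prx1_Cre against Tek_Cre and PC2 (25.5%) sets No_Cre against both, and the libraries of a group lie on top of each other.

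The use of immunoglobulin genes differed between groups and was shared by the 4 libraries of a group. Of the counts of Ig kappa V genes, which encode the variable part of antibody light chains, Igkv10-96 took 29.3 to 31.1% in the No_Cre libraries, Igkv6-32 took 17.5 to 18.5% in Tek_Cre and Igkv12-46 took 99.3 to 99.4% in Prx1_Cre. There were 13 V genes with at least 1% in No_Cre, 27 in Tek_Cre and 1 in Prx1_Cre, and 0 of them differed more than 2-fold between libraries of their group. The groups overlapped in part: 7 of the 13 No_Cre V genes had at least 1% in every Tek_Cre library as well, with Igkv10-96 at 8.46% there, and the 1 V gene of Prx1_Cre had at least 1% in Tek_Cre too. Across the 143 V genes with counts, Pearson's r of their shares was at least 0.998 within groups and -0.0157 to 0.272 between groups. V genes are similar in sequence, so single V genes are uncertain to the extent that reads were shared.

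**Figure D2:**
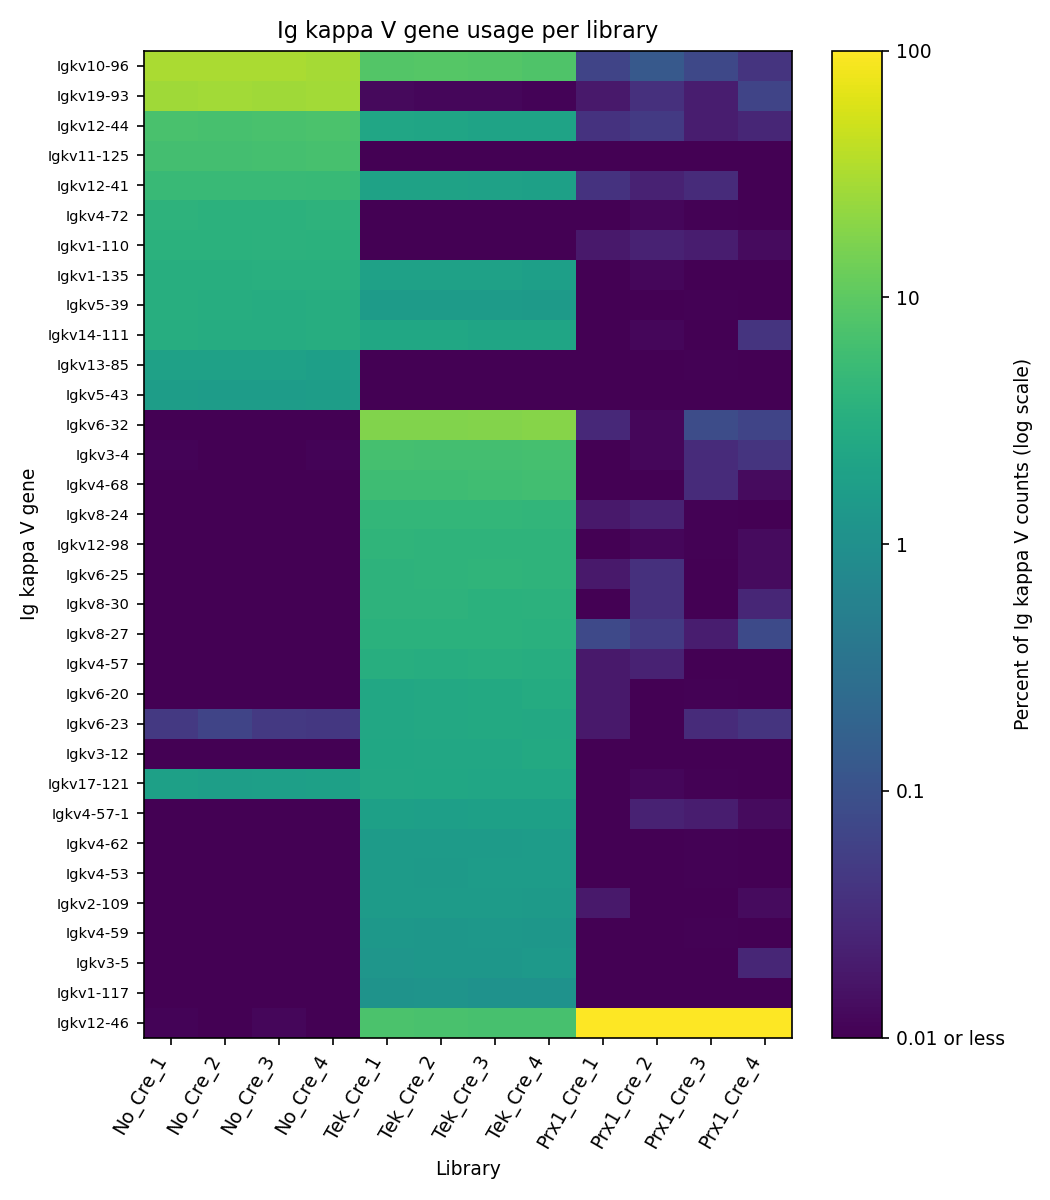
Share of each Ig kappa V gene in all Ig kappa V counts of a library, in percent on a log colour scale, for V genes with at least 1% in some library, with libraries as columns. Igkv12-46 takes 99.3 to 99.4% in the 4 Prx1_Cre libraries, and the 4 libraries of a group share their V gene use, while some V genes are used in both No_Cre and Tek_Cre.

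Prx1_Cre was compared with No_Cre to ask how the cells differed where Cre was active in the mesenchymal niche. In Prx1_Cre, cell cycle, erythroid and neutrophil genes were higher and stem cell, quiescence and B cell genes were lower. The S phase gene Ccne1, which encodes cyclin E1, was 4.14-fold higher (121 ± 4.75 against 29.1 ± 2.35 CPM, n = 4 each), and the erythroid transcription factor Klf1 was 8.83-fold higher (258 ± 16.8 against 29.1 ± 1.47 CPM). Ly6a, the stem cell surface antigen Sca-1, was 2.87-fold lower (75.1 ± 4.79 against 216 ± 12.4 CPM). The immediate early gene Egr1 was 2.96-fold lower (564 ± 7.57 against 1671 ± 64.8 CPM). Egr1 also fell in Tek_Cre against No_Cre (log2 fold change -0.42 ± 0.04), and immediate early genes served as a quality list. Ccne1 rose in Tek_Cre against No_Cre too (log2 fold change 0.76 ± 0.06, 49.5 ± 1.60 CPM in Tek_Cre), so its rise was not particular to Prx1_Cre. Of 14756 genes tested, 5411 rose and 5749 fell (4671 and 6540 with upper-quartile factors), with a median size of 0.64 on the log2 scale among these 11160, and 10123 (68.6%) had no overlap between the 2 groups, where chance gives 2.86%. Against a change of 2-fold, 762 genes rose and 1412 fell, of which 3 and 78 were immunoglobulin genes.

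Among the niche axis genes, Ezh2 (chromosome 6, 47530139 to 47595341, ENSMUSG00000029687.16), the histone methyltransferase of PRC2, rose from 57.2 ± 2.09 to 89.5 ± 8.28 CPM (log2 fold change 0.65 ± 0.06, adjusted p = 4.68e-10). Cdkn1a (chromosome 17, 29090976 to 29100727, ENSMUSG00000023067.13), the cell cycle inhibitor p21, rose from 20.6 ± 1.89 to 37.5 ± 1.51 CPM (0.86 ± 0.06, adjusted p = 1.35e-11). Cxcr4 (chromosome 1, 128588199 to 128592293, ENSMUSG00000045382.6), the receptor of Cxcl12, rose from 22.7 ± 0.733 to 26.8 ± 0.279 CPM (0.24 ± 0.06, adjusted p = 0.000564). Mki67 (chromosome 7, 135689784 to 135716361, ENSMUSG00000031004.8), a marker of cycling cells, rose from 104 ± 4.16 to 118 ± 5.89 CPM (0.19 ± 0.04, adjusted p = 0.000634). That call ended with upper-quartile factors, where the change was 0.09 (adjusted p = 0.0690). Bcr fell 2.84-fold to 7.69 ± 1.03 CPM (-1.51 ± 0.09) and Abl1 from 106 ± 3.41 to 74.4 ± 8.21 CPM (-0.51 ± 0.06). Whether reads of a fusion transcript, if the model has one, are among these counts is not known. Adjusted over the list alone, the calls were the same 6.

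Cxcl12 itself (chromosome 6, 117168535 to 117181367, ENSMUSG00000061353.11) was near the limit of detection in the sorted cells, at 0.366 ± 0.206 CPM in No_Cre, 0.390 ± 0.211 in Tek_Cre and 0.268 ± 0.183 in Prx1_Cre (36, 28 and 28 counts in all), and Ackr3 had 1, 0 and 9 counts. Neither passed the filter on low counts. Without that filter, Cxcl12 was not called in any comparison (log2 fold change -0.47 ± 0.43 with adjusted p = 0.394 for Prx1_Cre against No_Cre, -0.07 ± 0.43 with adjusted p = 0.992 for Tek_Cre against No_Cre and -0.40 ± 0.45 with adjusted p = 0.482 for Prx1_Cre against Tek_Cre). Ackr3 was called higher in Prx1_Cre than in Tek_Cre (adjusted p = 0.0131) and not in Prx1_Cre against No_Cre (adjusted p = 0.0605) or Tek_Cre against No_Cre (adjusted p = 0.465).

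**Figure D3:**
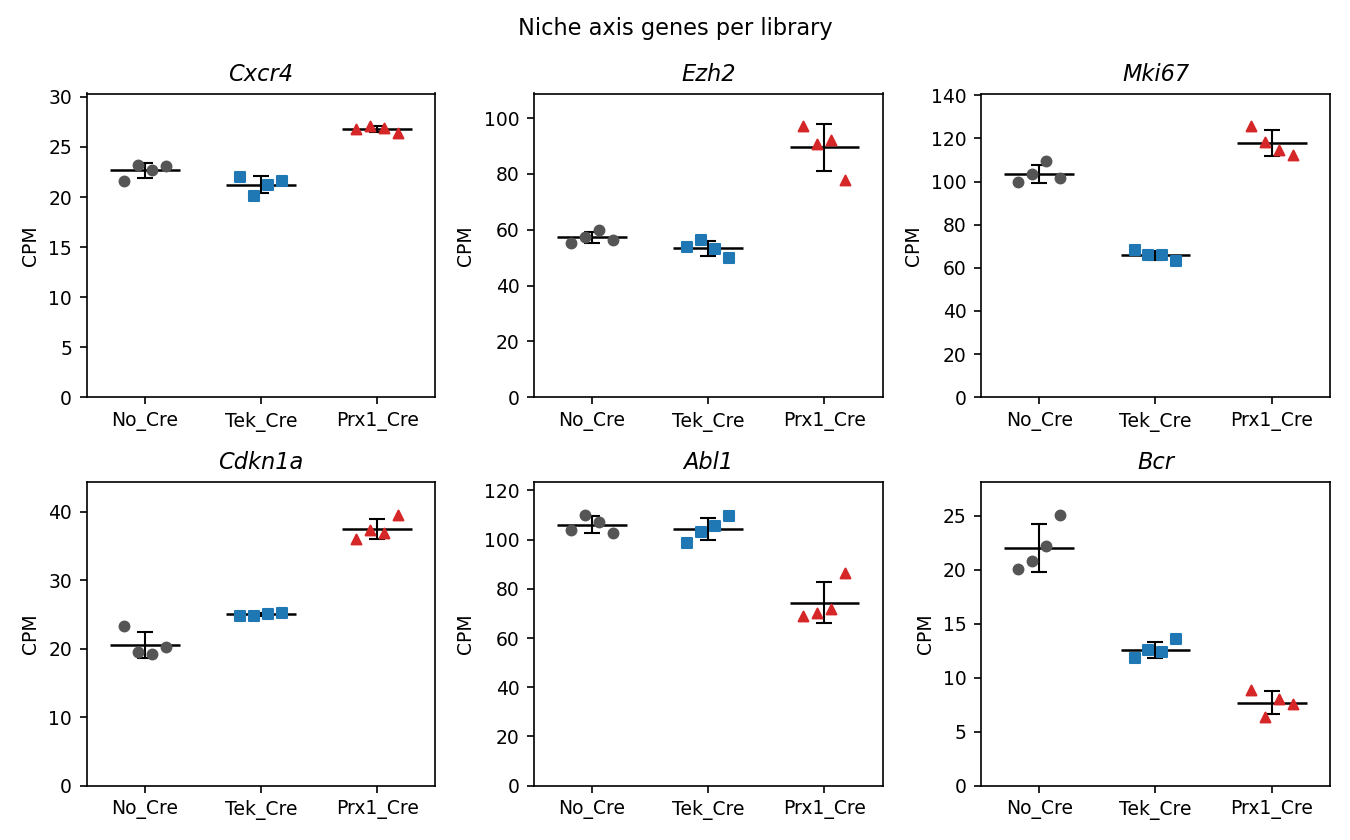
Level of 6 niche axis genes in CPM (linear axes from 0), with each point 1 library, the bar the group mean and the whisker the SD (n = 4). Ezh2 lies higher in Prx1_Cre (89.5 ± 8.28 CPM) than in No_Cre (57.2 ± 2.09) and Tek_Cre (53.3 ± 2.79), and Bcr lies highest in No_Cre.

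Proliferation lists rose together in Prx1_Cre. All 53 G2/M genes tested rose, with a median log2 fold change of 0.71 (adjusted p = 9.89e-14), among them Ccna2, which encodes cyclin A2, at 246 ± 12.7 against 113 ± 4.59 CPM, and Tacc3, a spindle protein, at 307 ± 6.70 against 158 ± 1.85 CPM. In the S phase list 43 genes rose, 1 fell and 2 were not called (median 0.59, adjusted p = 2.83e-09), and adjusted over the list alone 44 rose. The ribonucleotide reductase subunit Rrm2 was 2.44-fold higher and the replication licensing factor Cdc6 2.49-fold higher. Of 48 MYC targets 45 rose, 2 fell and 1 was not called (median 0.53, adjusted p = 5.00e-09), with the nucleolar protein Ncl at 1348 ± 40.9 against 694 ± 14.2 CPM and the polyamine enzyme Odc1 at 130 ± 2.83 against 66.6 ± 2.91 CPM. Of 34 DNA replication and repair genes 29 rose, 2 fell and 3 were not called (median 0.48, adjusted p = 7.51e-05, but adjusted p = 0.0589 with an estimated correlation), with Fancd2 2.67-fold higher. Heat shock and unfolded protein response genes rose in 24 of 30 cases, fell in 2 and were not called in 4 (median 0.60, adjusted p = 2.21e-08), led by the asparagine synthetase Asns, 8.09-fold higher, and with the chaperone Hspa5 2.23-fold higher.

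Genes of quiescence and of stem cells fell together. In the quiescence list 21 of 26 genes fell, 4 rose and 1 was not called (median -0.90, adjusted p = 4.16e-06). Txnip, a brake on glucose uptake, was 2.55-fold lower (283 ± 2.67 CPM in Prx1_Cre) and the RNA-binding protein Zfp36 2.15-fold lower, while Cdkn1a, a member of the same list, rose. In the same comparison 23 of 26 immediate early genes fell and all 7 mitochondrially encoded genes tested, of 13 listed, rose. Neither of these quality lists held with an estimated correlation. Handling was not told apart from lower quiescence. In the LTHSC list 32 of 38 genes fell, 3 rose and 3 were not called (median -0.83, adjusted p = 4.25e-12). Beside Ly6a, Pdzk1ip1 was 3.18-fold lower and Ifitm1 2.69-fold lower. Of 8 core LTHSC genes, a list made after the values were seen, 7 fell and 0 rose, with the transcription factor Mecom at 50.6 ± 1.81 against 94.0 ± 2.18 CPM, the endothelial protein C receptor Procr at 31.5 ± 2.19 against 74.5 ± 3.58 CPM and Hlf at 39.5 ± 1.65 against 79.9 ± 0.969 CPM. Of 20 megakaryocyte genes 16 fell and 4 were not called (median -0.49, adjusted p = 0.000335, but adjusted p = 0.0788 with an estimated correlation), with the platelet factor Pf4 2.80-fold lower. Of 20 multipotent progenitor genes 6 rose and 10 fell (median -0.11, adjusted p = 0.818).

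Beside these groups, markers of other blood cells moved apart in Prx1_Cre. All 22 erythroid genes rose (median 3.44, adjusted p = 4.46e-57), with the carbonic anhydrase Car1 10.4-fold higher (1698 ± 54.0 against 163 ± 4.38 CPM) and the blood group gene Rhd 16.7-fold higher. Late erythroid genes were at lower levels, with the heme enzyme Alas2 at 35.2 ± 1.55 against 1.21 ± 0.270 CPM and Hba-a2, near identical to its neighbour gene, at 35.5 ± 3.25 CPM in Prx1_Cre. Of 23 neutrophil genes 20 rose, 1 fell and 2 were not called (median 0.75, adjusted p = 2.88e-09), with myeloperoxidase Mpo at 11428 ± 818 against 4416 ± 84.7 CPM and the granule protease Ctsg at 801 ± 36.7 against 314 ± 3.99 CPM. In the list of mast cells, basophils and eosinophils 16 of 22 genes fell, 4 rose and 2 were not called (median -0.64, adjusted p = 0.000338), and 17 fell adjusted over the list alone. The eosinophil granule gene Epx was 5.26-fold lower (78.8 ± 7.18 against 414 ± 9.25 CPM), Prg2 3.70-fold lower and the mast cell tryptase Tpsb2 2.21-fold lower.

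All 18 B cell genes fell (median -4.28, which was the same with the 1 gene at 0 counts put at its bound, adjusted p = 7.40e-37), with the antibody constant gene Igkc 22.2-fold lower (790 ± 23.2 against 17572 ± 260 CPM) and the antibody joining chain Jchain 31.7-fold lower. The plasma cell markers Mzb1 and Sdc1 stood at 4.68 ± 0.491 against 46.3 ± 1.76 CPM and at 3.54 ± 0.170 against 26.0 ± 1.51 CPM. Of 14 T and NK cell genes 12 fell and 2 were not called (median -3.03, the same with 2 genes put at their bounds, adjusted p = 0.00824, but adjusted p = 0.162 with an estimated correlation), with Lck at 10.5 ± 0.647 against 24.8 ± 0.645 CPM and Nkg7 at 256 ± 4.19 against 370 ± 5.53 CPM. Of 26 genes of antigen presentation 23 fell, 2 rose and 1 was not called (median -0.77, adjusted p = 2.49e-13), among them the invariant chain Cd74, 12.1-fold lower, and the class II gene H2-Aa, 10.6-fold lower.

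Among the other called lists, 23 of 26 immediate early genes fell, 2 rose and 1 was not called (median -0.82, adjusted p = 2.89e-09, but adjusted p = 0.162 with an estimated correlation), with Fos at 2815 ± 147 against 6033 ± 155 CPM. Of 13 mitochondrially encoded genes listed 7 were tested, and all 7 rose (median 1.49, adjusted p = 0.00176, but adjusted p = 0.289 with an estimated correlation). Among them mt-Cytb stood at 1520 ± 257 against 420 ± 33.7 CPM. The list thus speaks for a part of these genes only. In the TGF-beta list 23 of 31 genes fell, 7 rose and 1 was not called (median -0.40, adjusted p = 0.0350, but adjusted p = 0.220 with an estimated correlation), with Ltbp3 3.26-fold lower. In the Wnt list 20 of 25 fell, 3 rose and 2 were not called (median -0.77, adjusted p = 0.0155, but adjusted p = 0.162 with an estimated correlation), with Tcf7l2 2.92-fold lower. In the interferon list 26 of 39 fell, 6 rose and 7 were not called (median -0.27, adjusted p = 0.0453, but adjusted p = 0.0862 with an estimated correlation), with Gbp2 2.46-fold and Oasl2 1.84-fold lower. That call was also lost with the stricter filter (adjusted p = 0.0531), with only the 8 libraries compared (adjusted p = 0.0562), without No_Cre replicate 2 (adjusted p = 0.0518) and without No_Cre replicate 3 (adjusted p = 0.0503).

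Among the largest changes outside immunoglobulin genes were those of genes at or near 0 in 1 group of the comparison. The actin-binding gene Avil (chromosome 10, 127000709 to 127020994) was at 45.8 ± 5.37 CPM in Prx1_Cre and had 0 counts in No_Cre, at least 1463-fold higher. The cysteine synthesis enzyme Cth stood at 27.6 ± 0.987 against 0.236 ± 0.103 CPM. Lower were Ly6d (0.0862 ± 0.0269 against 18.2 ± 0.871 CPM), the B cell receptor component Cd79a (0.194 ± 0.0995 against 22.3 ± 0.670 CPM) and the protease inhibitor Slpi, 22.4-fold lower (142 ± 10.4 against 3168 ± 48.9 CPM). Among immunoglobulin genes Igkv12-46 was 437-fold higher, Iglc1 stood at 0.0869 ± 0.0398 against 3807 ± 137 CPM, and Iglj1 and Igkv5-43 had 0 counts in Prx1_Cre, at least 4656-fold and 4300-fold lower.

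Of the 34 lists 19 were called in this comparison, 8 higher and 11 lower. With an estimated correlation 11 held, namely S phase, G2/M, MYC targets, erythroid, neutrophil and heat shock genes on the higher side, and quiescence, LTHSC, mast cell with basophil and eosinophil, B cell and antigen presentation genes on the lower side. The lists not called had members on both sides. PRC2 genes rose in 6 and fell in 5 of 12 cases (median 0.09), with Ezh2 among those that rose, p53 targets in 12 and 7 of 26 (0.27), apoptosis regulators in 7 and 9 of 23 (-0.09), BCR-ABL, STAT5 and RAS output in 9 and 15 of 27 (-0.26) and NF-kB and TNF genes in 12 and 13 of 29 (0.04). Adhesion and homing genes rose in 13 and fell in 13 of 34 cases (0.00), nuclear oxidative phosphorylation genes in 23 and 22 of 69 (-0.01), glycolysis genes in 13 and 8 of 25 (0.14), hypoxia genes in 10 and 9 of 23 (-0.13), cholesterol biosynthesis genes in 11 and 6 of 25 (0.14) and cytosolic ribosome genes in 22 and 20 of 73 (0.04). Monocyte, macrophage and dendritic cell genes rose in 13 and fell in 8 of 23 cases, where the median was 0.56 and the mean 0.12 while camera ranked the list lower (adjusted p = 0.495), endothelial genes in 8 and 10 of 20 (0.02) and stroma genes in 6 and 6 of 13 (0.28). Adjusted over the list alone, counts were within 1 gene of these in each list. The median, the mean or the test also differed in sign in the PRC2, apoptosis, endothelial, NF-kB, adhesion, oxidative phosphorylation, hypoxia and ribosome lists, none of them called. Beside these tests of a list against other genes, fry, which asks whether the genes of a list move one way on balance without setting them against other genes, called 29 lists.

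**Figure D4:**
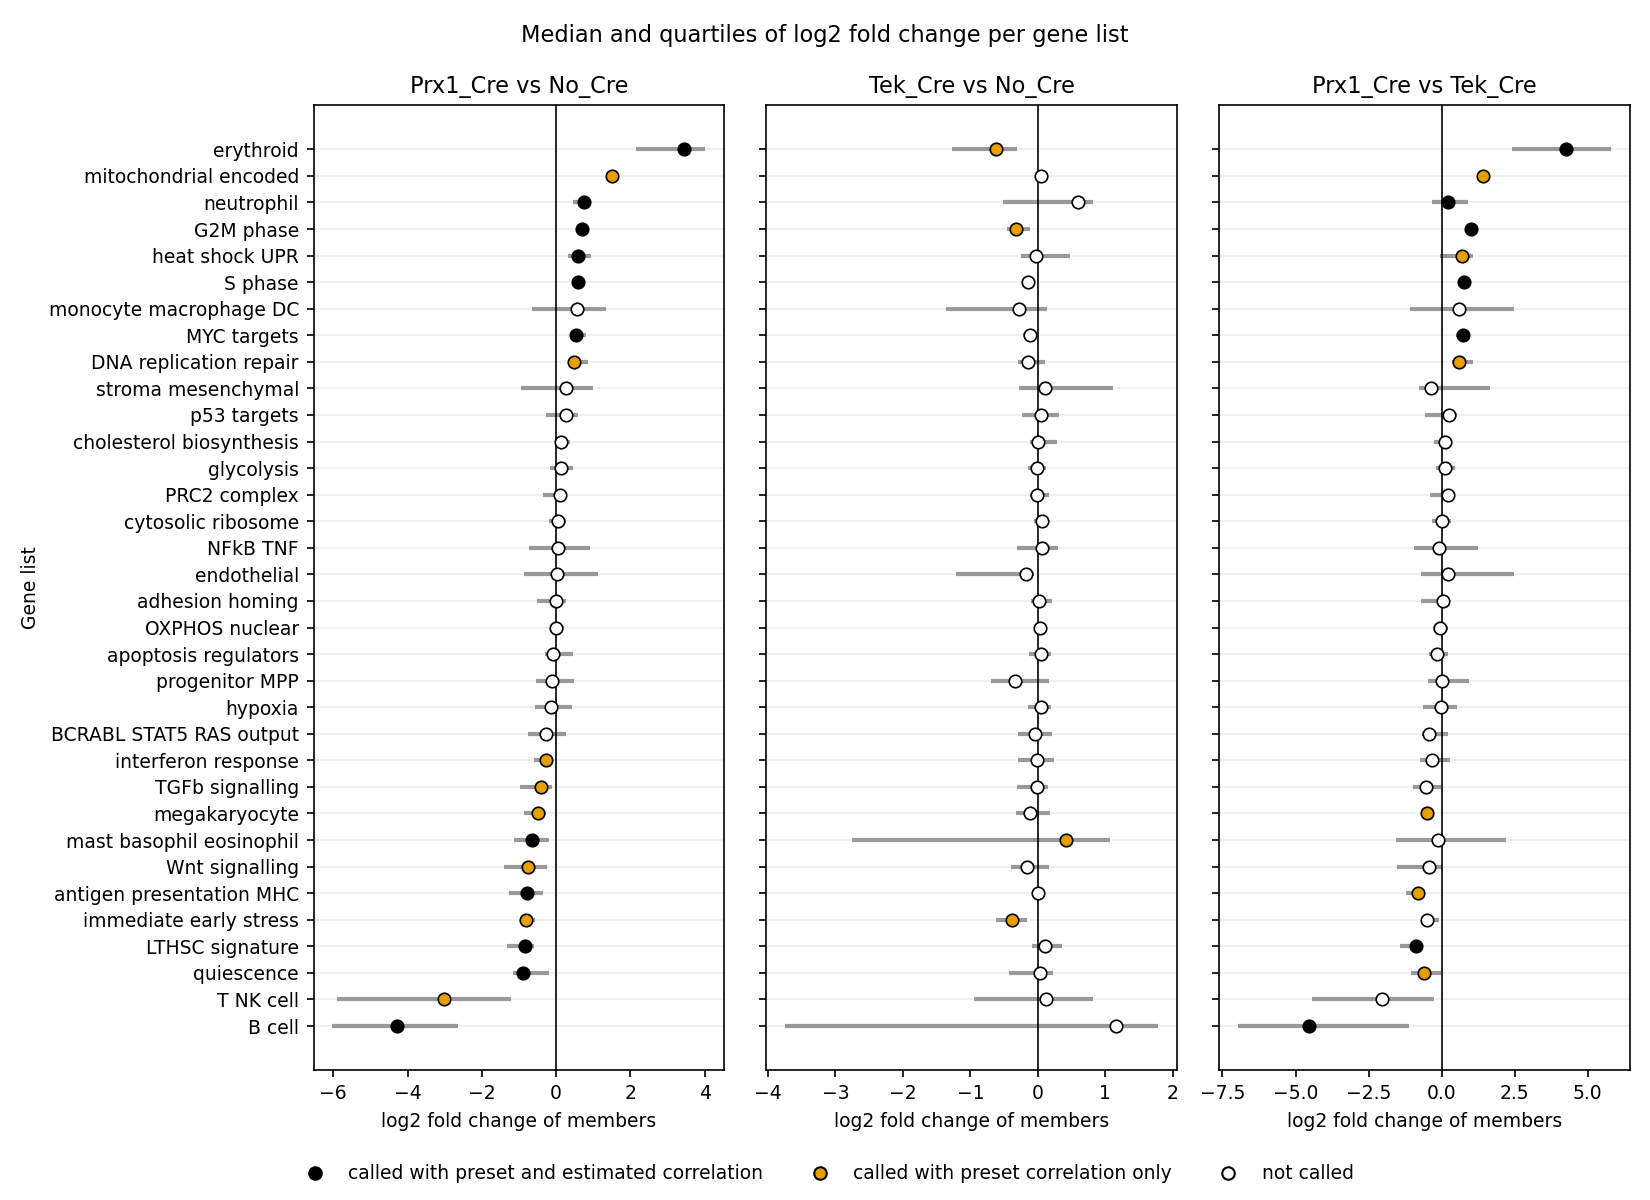
Median log2 fold change of each gene list (points) with the quartiles of its members (grey bars) in the 3 comparisons, each on its own linear axis. Filled black points were called with the preset and the estimated correlation, orange points with the preset alone and open points not at all, which gives 19, 4 and 13 called lists from left to right, 11, 0 and 7 of them black.

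Tek_Cre was compared with No_Cre to ask how the cells differed where Cre was active in endothelium and blood. In Tek_Cre, single genes of plasma cells and mast cells, chosen after the values were seen, were higher, while the B cell list was not called (adjusted p = 0.263), and the eosinophil granule genes Epx, Prg2 and Prg3 were lower. Erythroid and G2/M genes ranked lower too, but adjusted p = 0.140 and adjusted p = 0.157 with an estimated correlation. Igkc was 5.32-fold higher (93518 ± 2740 against 17572 ± 260 CPM, n = 4 each) and the mast cell chymase Cma1 2.12-fold higher (1304 ± 30.9 against 615 ± 12.5 CPM). The eosinophil peroxidase Epx was 144-fold lower (2.96 ± 0.711 against 414 ± 9.25 CPM), Car1 5.79-fold lower (28.1 ± 1.35 against 163 ± 4.38 CPM) and Mki67 1.58-fold lower (65.8 ± 2.15 against 104 ± 4.16 CPM). Of 14756 genes 3896 rose and 3911 fell, with a median size of 0.42 on the log2 scale, and 7189 (48.7%) had no overlap, where chance gives 2.86%. Against a change of 2-fold, 624 rose and 490 fell, of which 106 and 25 were immunoglobulin genes. With the number of genes detected as a covariate 4564 genes were called, 2307 higher and 2257 lower.

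Among the niche axis genes, Bcr fell (to 12.6 ± 0.735 CPM, log2 fold change -0.80 ± 0.09), Mki67 fell (-0.66 ± 0.05) and Cdkn1a rose (0.28 ± 0.07, adjusted p = 0.00106), and with the genes detected as a covariate its change was 0.27 ± 0.11, where the call ended with the larger SE (adjusted p = 0.0716). Cxcr4 (21.2 ± 0.813 CPM, -0.09 ± 0.06, adjusted p = 0.226), Ezh2 (53.3 ± 2.79 CPM, -0.11 ± 0.06, adjusted p = 0.149) and Abl1 (104 ± 4.52 CPM, -0.02 ± 0.06, adjusted p = 0.753) were not called. Without Prx1_Cre replicate 4, Ezh2 was called lower (adjusted p = 0.0370). Adjusted over the list alone, the same 3 genes were called.

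Of the 34 lists 4 were called, all ranked lower, and 0 were called with an estimated correlation, where 3 had an unadjusted p under 0.05, while fry called 25. In the G2/M list 39 of 53 genes fell, 1 rose and 13 were not called (median -0.33, adjusted p = 0.000564, but adjusted p = 0.157 with an estimated correlation), and 41 fell adjusted over the list alone. The mitotic kinase Aurka stood at 59.8 ± 1.30 against 91.7 ± 1.75 CPM and its activator Tpx2 at 89.7 ± 5.04 against 133 ± 4.32 CPM. In the erythroid list 18 of 22 genes fell and 4 were not called (median -0.62, adjusted p = 1.82e-06, but adjusted p = 0.140 with an estimated correlation), and 20 fell and 1 rose adjusted over the list alone. Klf1 was 2.91-fold lower and the sphingosine kinase Sphk1 12.7-fold lower. Of 26 immediate early genes 20 fell, 1 rose and 5 were not called (median -0.39, adjusted p = 0.000167, but adjusted p = 0.640 with an estimated correlation), with Atf3 4.22-fold, Nr4a1 2.19-fold and Klf6 1.56-fold lower.

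The list of mast cells, basophils and eosinophils split in Tek_Cre. Of its 22 genes 12 rose, 8 fell and 2 were not called, so that its median was 0.42 while its mean was -1.04 and camera ranked it lower (adjusted p = 0.00742, but adjusted p = 0.140 with an estimated correlation), and in 4 other settings camera ranked it higher without a call (adjusted p = 0.594 to 0.958). The eosinophil granule genes Prg2 and Prg3 fell 69.3-fold and 23.3-fold, to 16.0 ± 1.84 and 1.60 ± 0.302 CPM, and the lipoxygenase Alox15, which eosinophils express, fell 109-fold. Of 9 tested genes of an eosinophil list made after the values were seen, 8 fell and 0 rose (median -5.51). The mast cell proteases Cpa3 (600 ± 40.3 against 365 ± 15.8 CPM) and Tpsb2 (1954 ± 72.4 against 843 ± 13.6 CPM) rose.

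Neutrophil genes split as well, with 15 of 23 higher, 7 lower and 1 not called (median 0.60, adjusted p = 0.615). The early granule genes Mpo, Ctsg and Elane fell 3.94-fold, 5.10-fold and 2.85-fold, and the late granule collagenase Mmp8 rose 2.17-fold. In the LTHSC list 17 of 38 genes rose and 10 fell (median 0.10, adjusted p = 0.468), and of the 8 core LTHSC genes 6 rose and 1, Hlf, fell to 70.2 ± 1.91 CPM. Mecom rose to 129 ± 1.16 CPM and Procr to 90.8 ± 2.65 CPM. With the genes detected as a covariate, Procr (0.20 ± 0.08 against 0.29 ± 0.05, adjusted p = 0.0790) and Hlf (-0.18 ± 0.08 against -0.19 ± 0.04, adjusted p = 0.0939) were not called. In the quiescence list 8 of 26 genes rose and 10 fell (median 0.04, adjusted p = 0.353), and in the S phase list 2 of 46 rose and 22 fell (median -0.15, adjusted p = 0.290).

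Of single genes of antibody-secreting cells, chosen after the values were seen, Mzb1 stood at 231 ± 9.17 against 46.3 ± 1.76 CPM, Sdc1 at 138 ± 8.81 against 26.0 ± 1.51 CPM, Jchain at 874 ± 37.4 against 216 ± 6.63 CPM, and the plasma cell regulators Irf4 and Xbp1 at 28.8 ± 2.62 against 9.81 ± 0.673 CPM and 1161 ± 13.9 against 462 ± 4.04 CPM. In the B cell list 11 of 18 genes rose and 7 fell (median 1.16, mean -0.95, adjusted p = 0.263). The largest rises by the rule were all of immunoglobulin V genes, and outside them Nuggc was 16.2-fold higher (14.6 ± 2.26 against 0.881 ± 0.158 CPM), Rhpn2 9.91-fold and Dntt, the polymerase that adds untemplated bases to antigen receptor genes, 6.30-fold higher. Ighv2-6 had 0 counts in Tek_Cre against 86.4 ± 4.44 CPM in No_Cre, at least 2285-fold lower.

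**Figure D5:**
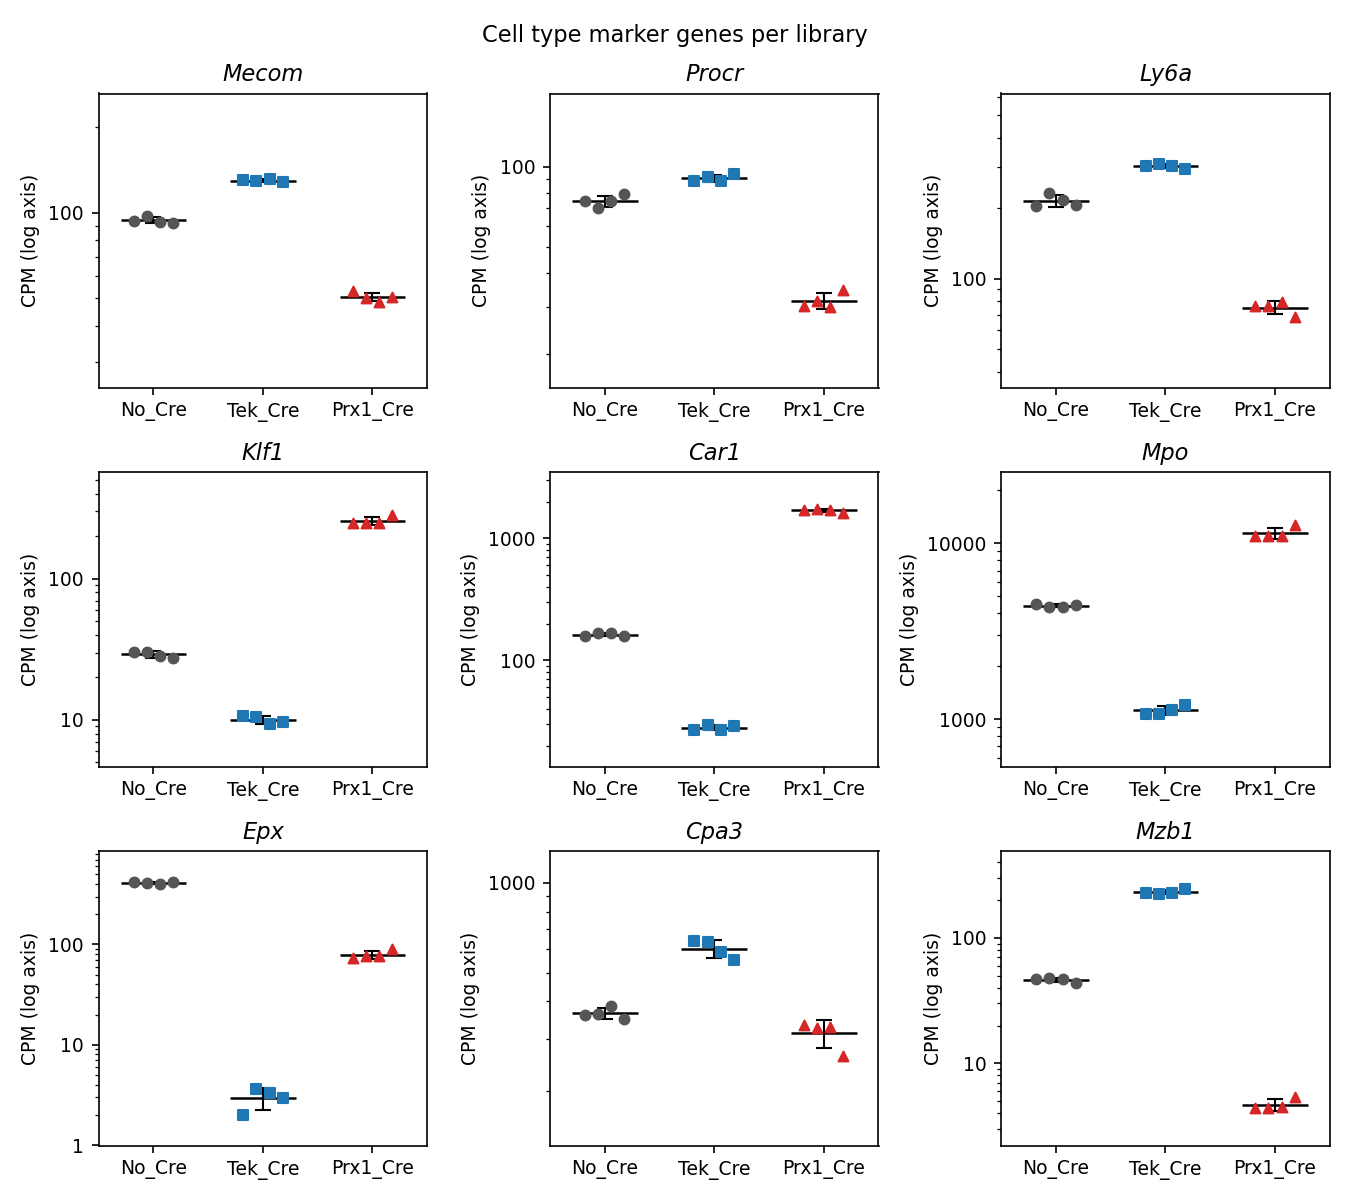
Level of 9 marker genes of stem cells (Mecom, Procr, Ly6a), erythroid cells (Klf1, Car1), neutrophils (Mpo), eosinophils (Epx), mast cells (Cpa3) and plasma cells (Mzb1), in CPM on log axes, with each point 1 library, the bar the group mean and the whisker the SD (n = 4). Klf1 and Car1 lie highest in Prx1_Cre, at 258 ± 16.8 and 1698 ± 54.0 CPM, and Mzb1 lies highest in Tek_Cre, at 231 ± 9.17 CPM.

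Prx1_Cre was compared with Tek_Cre directly, which is also the test of the difference between their contrasts with No_Cre. It compares sets of libraries that also differed in sex-linked genes. Whether they hold differences between mice is weighed in the closing section. Cell cycle, erythroid and neutrophil genes were higher in Prx1_Cre, and stem cell and B cell genes were higher in Tek_Cre. Car1 was 60.5-fold and Mpo 10.2-fold higher in Prx1_Cre, the spindle gene Tpx2 was 2.56-fold higher (229 ± 6.85 against 89.7 ± 5.04 CPM, n = 4 each), and Ly6a was 4.03-fold lower (75.1 ± 4.79 against 303 ± 6.26 CPM). Of 14756 genes 5571 rose and 5873 fell in Prx1_Cre, with a median size of 0.69, and 10233 (69.3%) had no overlap, where chance gives 2.86%. Against a change of 2-fold 1048 rose and 1824 fell, of which 2 and 137 were immunoglobulin genes.

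The axis genes Ezh2 (log2 fold change 0.75 ± 0.06), Mki67 (0.84 ± 0.05), Cdkn1a (0.58 ± 0.06) and Cxcr4 (0.33 ± 0.06) rose in Prx1_Cre against Tek_Cre, and Abl1 (-0.49 ± 0.06) and Bcr (-0.70 ± 0.10) fell. The differences in Ezh2 (adjusted p = 3.66e-11) and Cxcr4 (adjusted p = 2.03e-05) are thus tested between both Cre groups and do not rest on the controls. The same 6 genes were called over the list alone.

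All 53 G2/M genes rose (median 1.01, adjusted p = 8.20e-18), as did 42 of 46 S phase genes with 1 lower (median 0.78, adjusted p = 4.19e-09), 44 of 48 MYC targets with 1 lower (median 0.73, adjusted p = 4.19e-09) and all 22 erythroid genes (median 4.27, adjusted p = 4.88e-51). Neutrophil genes rose in 14 and fell in 8 of 23 cases (median 0.23, adjusted p = 0.000221), with Ctsg (log2 fold change 3.70) and Elane (2.31) among those that rose. LTHSC genes fell in 34 and rose in 1 of 38 cases (median -0.90, adjusted p = 2.60e-10), and B cell genes fell in 13 and rose in 3 of 18 (median -4.56, the same with 2 genes put at their bounds, adjusted p = 3.94e-26). These 7 calls held with an estimated correlation.

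The other 6 of the 13 calls did not. DNA replication and repair genes rose in 30 and fell in 2 of 34 cases (median 0.59, adjusted p = 8.17e-05, but adjusted p = 0.128 with an estimated correlation), with Fancd2 3.07-fold higher. Heat shock and unfolded protein response genes rose in 21 and fell in 7 of 30 (median 0.69, adjusted p = 0.00249, but adjusted p = 0.0866 with an estimated correlation), with Asns 10.4-fold and Hspa8 2.13-fold higher. The 7 mitochondrially encoded genes tested, of 13 listed, all rose (median 1.41, adjusted p = 0.0185, but adjusted p = 0.588 with an estimated correlation). Quiescence genes fell in 17 and rose in 4 of 26 (median -0.60, adjusted p = 0.0135, but adjusted p = 0.107 with an estimated correlation), with Txnip 3.11-fold lower. Megakaryocyte genes fell in 17 and rose in 1 of 20 (median -0.50, adjusted p = 0.0221, but adjusted p = 0.291 with an estimated correlation), with the platelet integrin Itgb3 at 127 ± 2.93 CPM in Prx1_Cre (log2 fold change -0.76). Antigen presentation genes fell in 22 and rose in 2 of 26 (median -0.82, adjusted p = 7.79e-08, but adjusted p = 0.130 with an estimated correlation), with Cd74 18.5-fold lower. Adjusted over the list alone, the counts of the 13 lists were the same.

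Beside these lists, Igkc was 118-fold and Jchain 128-fold lower in Prx1_Cre than in Tek_Cre, and Irf4 had 0 counts in Prx1_Cre, at least 1026-fold lower. Epx and Prg2 were 27.3-fold and 18.7-fold higher. Among the largest rises, Cth and the secreted Wnt antagonist Sfrp4 had 0 counts in Tek_Cre and were at least 729-fold and 610-fold higher.

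Across the 14756 genes, which are not independent replicates, the log2 fold changes of Prx1_Cre and of Tek_Cre against No_Cre had a Pearson's r of 0.0513 (covariance 0.110). This value differed in settings that also took in other genes. It was 0.263 by DESeq2, run without the filter on low counts, and 0.296 by edgeR without that filter (29159 genes). With the stricter filter (13374 genes) it was 0.0201. Sharing the same 4 controls alone gave r = 0.480 with a covariance of 0.0112 in simulated unchanged groups. With the controls split between both comparisons, r was 0.0557 to 0.0640 and the covariance 0.0722 to 0.0823. That covariance was lower than 0.110 although r was higher, so the fold changes with split controls were less spread. The split values are thus not directly comparable with the observed ones. Of genes called in both, 1405 rose in both where 1429 would if the calls were independent, and 1678 fell in both where 1524 would. There were 1534 genes that rose in Prx1_Cre and fell in Tek_Cre, where independent calls give 1434, and 1571 with the opposite pattern, where they give 1518. These expected numbers leave out that both comparisons share the No_Cre libraries.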

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

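The tests of the explanations below were chosen after the results were seen. The comparisons with other splits of the libraries were planned before the data were examined. An exception is the one for genes beyond a 2-fold change, a test chosen after the values were seen.

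A library far from the other 3 of its group was looked for in 18 combinations of library measure and group and 267 of gene and group, where chance marks about 1 in 20. It was found in 2 and 26 of them. Prx1_Cre replicate 4 held 15 of the 26, beside a share of the 20 most abundant genes of 8.84% and a TMM factor of 1.06. Its values lay above the rest of the group for Abl1 (86.6 CPM), Alas2 (37.5), Elane (3398), Fos (3033), Igkc (825), Klf1 (283), Mpo (12654), Mzb1 (5.42), Rhd (343) and Sphk1 (277), and below it for Asns (489), Cpa3 (263), Hspa5 (1569), Igkv12-46 (312) and Ncl (1287). In the other libraries the values apart were those of Alox15 in Prx1_Cre replicate 2 (25.7 CPM), Ackr3 and Sfrp4 in No_Cre replicate 4 (0.0461 and 0.415), Asns, Hspa8 and Tpx2 in No_Cre replicate 3 (65.1, 266 and 139), Fancd2 in No_Cre replicate 1 (21.6) and Hlf in No_Cre replicate 2 (78.5). In Tek_Cre they were Aurka and Ccna2 in replicate 4 (61.7 and 90.7) and Prss50 in replicate 2 (0.0739). No biological explanation was tested for these.

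The libraries of a group varied little, with a biological coefficient of variation of 3.45% to 6.81%, and shared 1 set of Ig kappa V genes. The series text calls them biological replicates, yet 4 separately sampled mice, each with its own plasma cell clones, would differ in V genes, and the largest ratio between libraries of a group over 41 combinations of V gene and group was 1.15. A single library deposited 4 times is argued against by a chi-square per degree of freedom of 1.80 to 7.80 for 15 pairs within groups and 11.5 to 14.3 for the 3 pairs with Prx1_Cre replicate 4, where counting error alone gives about 1. Libraries made from 1 pool of cells or RNA per group may be the source, since V gene shares correlated at 0.998 or more within groups and at most 0.272 between them. If so, the p-values describe the making of libraries and not mice, and each group is a single sample of mice.

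Immunoglobulin genes were high in Tek_Cre, intermediate in No_Cre and low in Prx1_Cre. A candidate source is plasma cells or their RNA in the sorted material, although sorting with conventional cell surface markers should remove them. A list of 20 plasma cell genes was written before this test but after the values were seen, and of the 8 that are neither immunoglobulin genes nor in a fixed list or among the named genes, 7 rose in Tek_Cre. The most abundant members stood at 130323 (Ighg1), 93518 (Igkc), 1161 (Xbp1) and 874 CPM (Jchain) in Tek_Cre, 10 of the 20 also stood at 5 CPM or more in Prx1_Cre, and 4 are in the B cell list. The Cre group cannot be told apart from a pool or sort that the libraries of a group may share. Libraries of different groups differed at least 16.7 times as much as those of the same group.

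Cell cycle and erythroid genes were higher and stem cell genes lower in Prx1_Cre. A few genes taking most of the counts moves all other genes by 1 factor, which leaves the gap between lists as it is. The medians of the G2/M and LTHSC lists lay 1.54 apart on the log2 scale. The lower quartile of the first was at 0.52 and the upper quartile of the second at -0.58. This gap follows from the calls of both lists, so it is no separate test of that explanation. A lower share of stem cells alone is argued against, since it would raise the markers of every other blood cell type. Of 7 such lists 4 were called lower, of which B cells and mast cells with basophils and eosinophils held. Megakaryocytes (adjusted p = 0.0788 with an estimated correlation) and T and NK cells (adjusted p = 0.162 with an estimated correlation) did not hold. A larger share of erythroid and neutrophil progenitors stays open, as do handling and sex, since the mitochondrial share was 0.388% against 0.133% in No_Cre, 23 of 26 immediate early genes fell (adjusted p = 0.162 with an estimated correlation), and Xist stood at 15.2 against 1.55 and Ddx3y at 6.69 against 21.4 CPM. Here, too, the Cre group cannot be told apart from a pool or sort that the libraries of a group may share, with the same ratio of 16.7.

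Other splits of the 8 libraries of a comparison, 35 with the real one, were compared with the real split. They bear on how these libraries fall into groups, and if each group is 1 pool they say nothing of chance between mice. For genes called, the real split stood out in each comparison. It gave 11160, 7807 and 11444 genes for Prx1_Cre and No_Cre, for Tek_Cre and No_Cre and for Prx1_Cre and Tek_Cre. The highest other split gave 0 by edgeR, so that 1 split of 35 was as large. Every other split counts the group difference as spread within its groups. The result thus restates that the libraries separate by group, and it does not exclude chance. At an unadjusted p under 0.05 the highest other splits had 3103, 1952 and 3274 genes, against 11349, 8519 and 11625. For genes beyond a 2-fold change the real split stood out in the same way and with the same limit, with 2174, 1114 and 2872 genes against 0. With an unadjusted p under 0.05 the highest other splits had 54, 74 and 51 against 2634, 1478 and 3284. For gene lists called, the splits cannot decide on chance, since a split that exchanges 1 library still carries part of the group difference. As many lists were called in 11, 15 and 12 of the 35 splits. The real splits had 19, 4 and 13 lists and the highest other 19, 6 and 16. The other splits as large each exchanged 1 library, and the 18 splits that exchanged 2 gave at most 1 list.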

How the results depend on the processing

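The test against a 2-fold change, the fit without immunoglobulin genes and the genes added to the named ones were chosen after the data were seen. Against a 2-fold change, Prx1_Cre and No_Cre differed in 2174 genes (762 higher, 1412 lower), Tek_Cre and No_Cre in 1114 (624 and 490), Prx1_Cre and Tek_Cre in 2872 (1048 and 1824), and 1 of the 15 calls of niche axis genes was left, because the test asks for a larger change. With an estimated correlation 11, 0 and 7 lists were called in these comparisons, and fry called 29, 25 and 30. In Tek_Cre and No_Cre, lists called numbered 9 with limma-voom, 11 without a filter, 8 with the replicate block, 12 with genes detected as a covariate and 10 without immunoglobulin genes, against 4. With that covariate 4564 genes were called there, 2307 higher and 2257 lower. The list of mast cells, basophils and eosinophils had medians of 0.423 with limma-voom, 0.403 without a filter, 0.422 with the replicate block and 0.434 with the covariate in that comparison, where camera ranked it higher (adjusted p = 0.594, 0.679, 0.958 and 0.839). The correlation of the log2 fold changes of Prx1_Cre and of Tek_Cre against No_Cre was 0.263 with DESeq2, 0.296 without a filter and 0.0201 with the stricter filter. Upper-quartile factors gave 4671 genes higher and 6540 lower in Prx1_Cre and No_Cre, 3682 and 4161 in Tek_Cre and No_Cre, and 4954 and 6490 in Prx1_Cre and Tek_Cre. Apart from the 2-fold test, the cause was not tested.

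Leaving out each library in turn gave 10941 to 11485 genes in Prx1_Cre and No_Cre (5283 to 5523 higher, 5654 to 5962 lower, 18 to 20 lists), 7356 to 8696 in Tek_Cre and No_Cre (3594 to 4252 and 3671 to 4444, 4 lists each time) and 11304 to 11788 in Prx1_Cre and Tek_Cre (5492 to 5750 and 5770 to 6038, 13 to 14 lists). The correlation was 0.0484 to 0.0770, and 15 to 16 niche axis calls were made. Among single genes, 40 were lost against a 2-fold change, 3 with the covariate and 1 with upper-quartile factors, and 1 was gained without Prx1_Cre replicate 4. Cxcl12 and Ackr3 were tested only without a filter, where Ackr3 was called in Prx1_Cre and Tek_Cre (adjusted p = 0.0131) and Cxcl12 in none, with SEs of 0.43 to 0.45 on the log2 scale.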

Other observations

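All tests in this part were chosen after the values were seen. Erythroid genes of both stages moved together. Of 12 early erythroid genes, 11 rose in Prx1_Cre against No_Cre (median log2 fold change 2.86) and 9 fell in Tek_Cre against No_Cre (median -0.50). Of 12 late ones, 12 rose in Prx1_Cre (median 3.67) and 11 fell in Tek_Cre (median -1.26). Eosinophil genes were lowest in Tek_Cre: of 9 tested, 7 fell in Prx1_Cre against No_Cre (median -0.96), and 9 rose in Prx1_Cre against Tek_Cre (median 4.23). Of 8 core LTHSC genes 8 fell in Prx1_Cre against Tek_Cre (median -1.37). Plasma cell genes fell in 18 of 20 cases in Prx1_Cre against No_Cre (median -3.28) and in 20 of 20 against Tek_Cre (median -5.44).

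Sex-linked genes differed between the groups. Xist, made from the inactive X chromosome of female cells, stood at 1.55 ± 0.0394 CPM in No_Cre, 1.48 ± 0.200 in Tek_Cre and 15.2 ± 1.47 in Prx1_Cre, and the Y-linked Ddx3y at 21.4 ± 1.27, 24.9 ± 1.58 and 6.69 ± 0.633 CPM (mean ± SD, n = 4). Of 5 sex-linked genes 1 rose and 4 fell in Prx1_Cre against No_Cre. Xist and Ddx3y were both present in each of the 12 libraries. Across the Prx1_Cre libraries Xist ran from 13.3 to 16.5 CPM and Ddx3y from 6.09 to 7.58 CPM. The labels state no sex.

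Libraries with the same number in different groups were compared by the correlation of their deviations from the group means across genes, which are not independent replicates. It was -0.0322 to 0.204 over 12 pairs with the same number, 2 of them over 0.1. Both of these held Prx1_Cre replicate 4, the library farthest from its group (0.204 with Tek_Cre replicate 4 and 0.106 with No_Cre replicate 4). Over 36 pairs with different numbers the correlation was -0.135 to 0.0602. Of the 12 libraries 9 correlated best with their own number, a count that was not set against chance.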
